A study of Mus musculus with 6 samples.

How the data were processed

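Total RNA of liver tissue from C57BL/6 mice was measured on arrays after labelling with a GeneChip terminal labelling kit, per the labels. The 6 arrays fall into RD and HFD by the sample labels, with 3 biological replicates per diet, and each diet lasted 2 days. All 6 sample titles also carry the letters NI, which the labels do not explain, so a condition shared by all arrays is not known here. The deposited table holds 1 log2 value per probe set and array; the summarisation and normalization methods are not given in the sources used here. Base 2 was inferred from the values, which run from 2.28 to 14.86, because natural or base-10 logs of that size would exceed the range of a scanner. The array medians of 7.06 to 7.11 are close and not identical, and values were used as deposited. Detection calls, scan dates and batches were not used here, so background and batch effects were not tested. Centring and scale between arrays therefore rest on the authors' unstated steps. No depth applies to arrays, and their number limits the precision.

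Probe sets were named through the platform's annotation table, which can be old. Of 35512 rows, 23410 were listed with a gene, 21789 with 1 symbol and 1621 with several, and 12102 were not listed, which leaves them unnamed here. Gene identifiers of 21698 probe sets with 1 symbol were matched to RefSeq names of the mouse assembly GRCm38.p6, which changed 0 symbols. The build behind the annotation is not given in the sources used here, so no coordinates are printed. Probe sets with several symbols or none were left out of the tests of genes. For the 999 genes with more than 1 probe set, the one with the highest mean over all 6 arrays was used, which left 19938 genes. No filter on dim probe sets was applied. The brightest probe set of a gene can also bind close copies elsewhere in the genome.

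Each gene was fitted with diet alone in limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are HFD minus RD on the log2 scale, with the moderated SE. Lists of genes were tested with camera at its preset inter-gene correlation of 0.01, adjusted over 43 lists, of which 29 are processes and 14 are cell type markers. Camera with an estimated correlation and fry, both in limma, were run beside it. Members past the threshold were counted over all genes tested and adjusted over the list alone. The lists, the tests, the alternatives and the rule for naming genes were chosen before the data were examined.

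Genes are named by this rule. Part 1 takes the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05 and no overlap between the diets. Predicted genes, by symbol, are counted and not named, as are microRNA, small nucleolar RNA, olfactory and vomeronasal receptor genes. Had fewer than 12 passed in a direction, all that passed would have been named, filled up to 6 with those of the smallest p, said not to pass. Part 2 takes up to 4 members of each list with the smallest unadjusted p. Any gene outside the rule is said to be chosen after its values were seen.

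The steps were checked on simulated data with the spread of these arrays, in which 200 of 19938 genes were changed for HFD against RD. Recovery was 59.7% for a log2 change of 0.5, 91.0% for 1 and 98.5% for 2. Of 179 calls, 13 were of unchanged genes. With no list changed, camera called 0 lists, and a list lowered by 0.5 was called with both correlations. The simulated genes varied independently, so this says nothing on lists of correlated genes. Alternatives covered quantile normalization, median centring, the brighter genes only, the mean of all probe sets of a gene, every row of the table, an intensity trend with a robust prior, array weights, the replicate number as a block, an unmoderated linear model, thresholds with a fold of 1.5, and each array left out in turn. All per-sample value columns were used.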

Results

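Liver transcripts were measured in C57BL/6 mice, an inbred laboratory strain, after 2 days on a regular diet (RD) or on a high fat diet (HFD). Each diet had 3 biological replicates and each replicate had its own array, so 6 arrays of total RNA from frozen liver tissue were compared. Expression values were log2 signals of 35512 probe sets, and 19938 genes were tested. Array medians lay between 7.06 and 7.11. The number of arrays limits the precision of every value. The comparison of the diets asks how gene expression in the liver differs after 2 days on HFD. The composition of the diets was not used here, so the differences cannot be assigned to fat itself.

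The arrays separated by diet. Across genes, which are not independent replicates, Pearson's r between arrays was 0.996 to 0.997 within a diet and 0.991 to 0.994 between diets. The leading principal component held 51.4% of the variance and placed the RD arrays between -16.5 and -14.5 and the HFD arrays between 12.6 and 21.5. HFD replicate 1 lay farthest out, at 21.5, against 12.7 and 12.6 for the other HFD arrays.

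**Figure D1:**
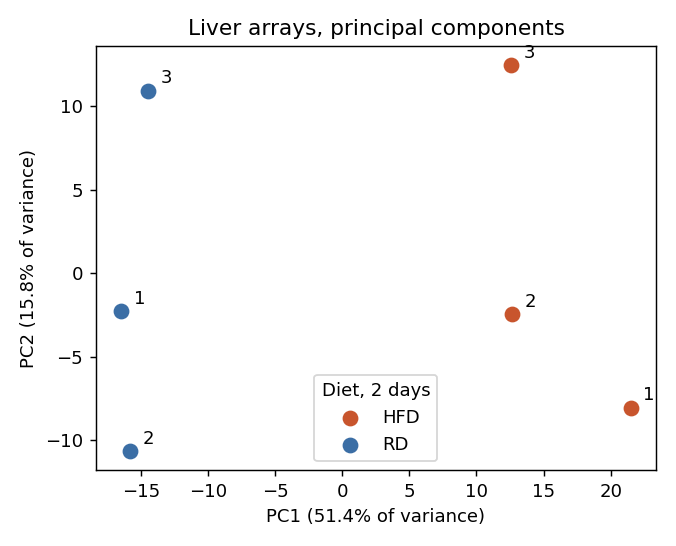
Position of the 6 liver arrays on the leading 2 principal components of log2 expression, with the share of variance on each axis; colour gives the diet and the number beside each point the replicate. The RD arrays lie between -16.5 and -14.5 on the horizontal axis and the HFD arrays between 12.6 and 21.5.

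After 2 days of HFD, the bile acid synthesis genes Cyp8b1 and Cyp7a1 and the genes of cholesterol synthesis fell. Targets of the transcription factor NRF2, serum amyloid genes and several detoxifying enzymes rose. The largest fall was that of Cyp8b1 (probe set 10597875), the sterol hydroxylase needed to make cholic acid, whose log2 expression went from 12.51 ± 0.11 in RD to 6.63 ± 0.12 in HFD (SD, n = 3 each). That is a fall of 58.9-fold, from the 97.6th to the 34.6th percentile of all genes. Cyp7a1 (probe set 10511375), the rate-limiting enzyme of bile acid synthesis, fell by 28.7-fold, from 11.55 ± 0.55 to 6.71 ± 0.55. Detection calls were not used here, so whether the HFD values of this pair lie at background is open, and a value at background would understate the fold.

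In all, 621 genes were higher and 446 lower in HFD (limma, Benjamini-Hochberg adjusted p under 0.05), of 3926 with an unadjusted p under 0.05. The 3 HFD values did not overlap the 3 RD values in any of these 1067 calls. Non-overlapping values were seen for 25.7% of all genes, against 10% by chance. A change of at least 2-fold was reached by 51 of the higher and 47 of the lower genes. Centring each array on its median gave 726 higher and 384 lower genes and raised the share of higher calls from 58.2% to 65.4%. Leaving out an array moved both counts by over 1.5 times. Higher genes numbered 197, 227 and 353 without RD replicate 1, 2 or 3 and 299, 371 and 366 without HFD replicate 1, 2 or 3. Lower genes numbered 216, 178 and 273 without the same RD arrays and 213, 240 and 251 without the same HFD arrays.

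Among the 12 largest rises, Gadd45b (probe set 10364950), a stress-inducible gene, led with a log2 difference of 2.07 ± 0.15 (SE; adjusted p = 3.6e-04). It was followed by the drug-metabolizing cytochrome Cyp2c55 (2.02 ± 0.21), the acute phase gene Saa2 (2.01 ± 0.17), the retinoic acid hydroxylase Cyp26a1 (1.99 ± 0.22) and Slc51b (1.98 ± 0.08), a subunit of the basolateral bile acid exporter. Saa3 rose by 1.95 ± 0.28, the efflux pump Abcb1a by 1.86 ± 0.16 and Prrg4 by 1.75 ± 0.17. The carbonyl reductase Cbr3 rose by 1.59 ± 0.15, the quinone reductase Nqo1 by 1.59 ± 0.14, Saa1 by 1.58 ± 0.25 and the retinol dehydrogenase Dhrs9 by 1.49 ± 0.16. Saa1 and Saa2 are near-identical paralogs, so their separate values are uncertain.

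Among the 12 largest falls, 5 besides Cyp8b1 and Cyp7a1 belong to cholesterol synthesis: Sqle (-2.84 ± 0.13), Idi1 (-2.51 ± 0.17), Nsdhl (-2.21 ± 0.07), Msmo1 (-2.17 ± 0.13) and Cyp51 (-1.94 ± 0.20). The others were the fatty acid binding protein Fabp5 (-2.58 ± 0.23), the steroid hydroxylase Cyp17a1 (-2.41 ± 0.23), the betaine-homocysteine methyltransferase Bhmt (-2.31 ± 0.18), Raet1d (-2.09 ± 0.17) and the aldolase Aldoc (-1.79 ± 0.10). Fabp5 and Idi1 were each measured by 2 probe sets and Bhmt by 3, and the probe sets of each gene fell alike, by -2.58 and -2.57 for Fabp5, -2.51 and -2.59 for Idi1, and -2.31, -2.30 and -2.14 for Bhmt. Each of the 24 largest rises and falls kept an adjusted p under 0.05 when any 1 array was left out.

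**Figure D2:**
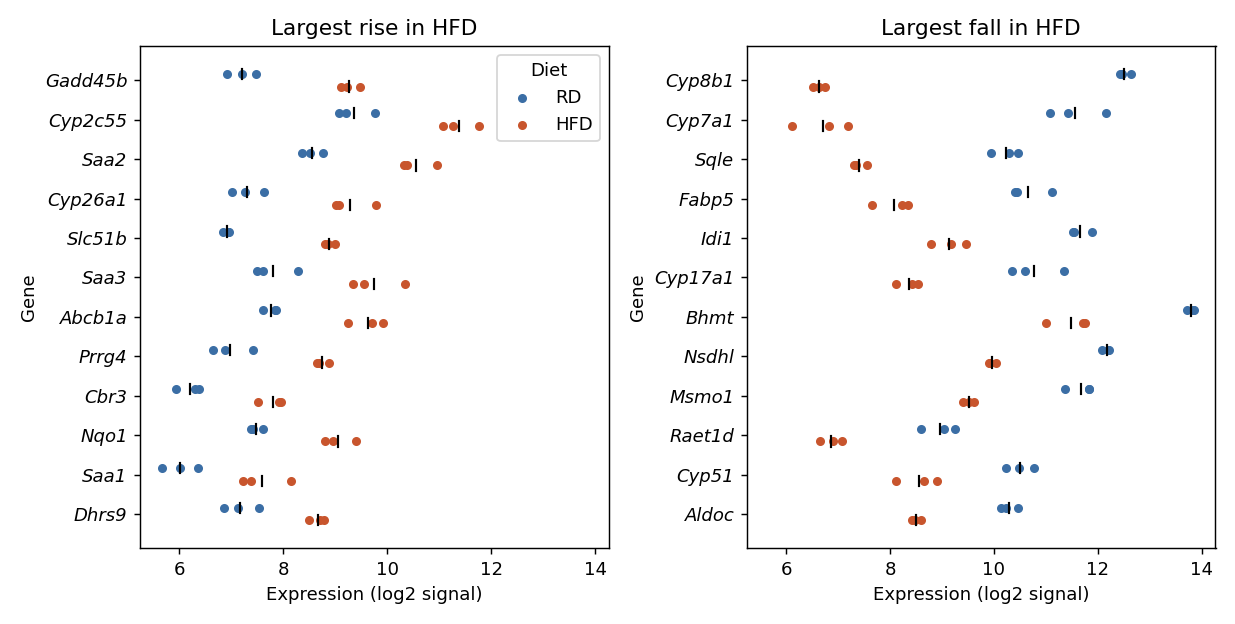
Log2 expression of the 12 genes with the largest rise and the 12 with the largest fall after 2 days of HFD; points are single arrays (3 per diet) and black ticks are the means of a diet. In each of the 24 genes the RD and HFD points do not overlap, and Cyp8b1 goes from a mean of 12.51 to 6.63.

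Cholesterol synthesis fell as a whole. Of the 17 enzymes measured, 17 were lower in HFD, with a median log2 difference of -1.10 and a range from -2.84 for Sqle to -0.59. Fdps, the farnesyl diphosphate synthase, fell by 1.71 ± 0.11 on the log2 scale. Adjusted over the list alone the count was also 17, and without 1 array it was 16 or 17. Camera, which compares a list with all other genes, called the list lower (adjusted p = 9.1e-33), but the call was lost with an estimated correlation between genes (adjusted p = 0.115 with an estimated correlation). Of 7 genes of SREBP2 regulated uptake and feedback, 5 fell, also 5 adjusted over the list alone, with a median of -0.41. The sterol carrier Stard4 (-1.12 ± 0.09) and Rdh11 (-0.81 ± 0.07) were among them. Camera called this list lower (adjusted p = 7.0e-05; adjusted p = 0.115 with an estimated correlation). Its count was 2 without RD replicate 1 or 2 or each single HFD array.

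Most genes of de novo lipogenesis that passed fell. Among its 21 genes 11 fell and 1 rose (15 and 2 adjusted over the list alone), and the median was -0.47. The acetyl-CoA carboxylase Acacb fell by 1.30 ± 0.08, the acetyl-CoA synthetase Acss2 by 0.98 ± 0.07 and the elongase Elovl5 by 0.70 ± 0.08 on the log2 scale. The gene that rose was Srebf1, the sterol-responsive factor that drives lipogenic enzymes, at 0.97 ± 0.22 (adjusted p = 0.040). It is named after its values were seen, and its call held only without RD replicate 3 when 1 array was left out (adjusted p up to 0.102). Camera called the list lower (adjusted p = 4.7e-11; adjusted p = 0.170 with an estimated correlation), and 7 members fell without RD replicate 1.

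Bile acid synthesis and transport moved in both directions. Of 26 genes 6 rose and 5 fell, and adjusted over the list alone 8 rose and 10 fell. Beside Slc51b, the sterol export transporter gene Abcg5 rose by 1.11 ± 0.06. Chosen after their values were seen, its partner Abcg8 rose by 1.09 ± 0.08 and Nr0b2, a nuclear receptor that represses bile acid synthesis, by 1.13 ± 0.12. Nr1h4, the bile acid receptor and likewise chosen after its values were seen, fell by 0.73 ± 0.10 on the log2 scale. The list as a whole was not called by camera (adjusted p = 0.682, median -0.04), while fry called it lower (adjusted p = 0.014). Without RD replicate 1 or 2 or HFD replicate 1 or 3, 3 members of the list fell. Its median was -0.07 without each single HFD array.

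Fatty acid oxidation lists held few calls. In the mitochondrial list of 20 genes 1 fell (3 adjusted over the list alone), Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, at -0.33 ± 0.06. That call was lost whichever array was left out (adjusted p up to 0.082). The list's median was -0.10 and camera called it lower (adjusted p = 0.018; adjusted p = 0.296 with an estimated correlation), a call lost without HFD replicate 2 (adjusted p = 0.071). Of 22 genes of peroxisomal and omega oxidation 3 rose and 2 fell (4 and 4 adjusted over the list alone), with no call by camera (adjusted p = 0.130). The peroxisomal bifunctional enzyme Ehhadh rose by 1.05 ± 0.10 and Nudt19 by 0.59 ± 0.07, while the transporter Abcd3 fell by 0.54 ± 0.06 on the log2 scale, and 1 member fell without each single RD array or HFD replicate 1. Only 1 of 4 ketone body genes fell, Bdh1 (-0.34 ± 0.06; 2 adjusted over the list alone), and it passed the test only without HFD replicate 3 when 1 array was left out. Camera called that list lower (adjusted p = 0.040; adjusted p = 0.251 with an estimated correlation), a call lost without RD replicate 1 or 3 or HFD replicate 3 (adjusted p up to 0.123). Among 28 genes of PPAR responsive lipid storage and signalling 1 rose and 5 fell (2 and 9 adjusted over the list alone), with the lipid droplet proteins Fitm1 (-0.75 ± 0.08) and Fitm2 (-0.59 ± 0.08) at the smallest p. Camera's call of this list as lower (adjusted p = 0.048; adjusted p = 0.423 with an estimated correlation) was lost without RD replicate 2 or 3 or HFD replicate 1 or 2 (adjusted p up to 0.150). In it 3 members fell without RD replicate 2 or each single HFD array, and 0 rose without each single RD array. In the lipoprotein list 2 of 17 genes rose and 1 fell (4 and 2 adjusted over the list alone), the phospholipid transfer protein Pltp (-1.08 ± 0.11), with no call by camera (adjusted p = 0.581); 0 rose without RD replicate 2 and 1 without RD replicate 1 or HFD replicate 1 or 2.

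NRF2 targets rose together. Of 24 measured, 20 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 0.76. Sulfiredoxin Srxn1 rose by 1.46 ± 0.07, the glutathione transferase Gsta4 by 1.27 ± 0.08 and the haem oxygenase Hmox1 by 1.13 ± 0.10. Gstm3 rose by 1.03 ± 0.09 on its brighter probe set and by 1.61 ± 0.13 on the other. Between 15 and 18 members rose without 1 array. Camera called the list higher (adjusted p = 2.0e-23; adjusted p = 0.115 with an estimated correlation). Other antioxidant enzymes and oxidant sources did not move as a group, since 1 of 24 rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.789; median 0.05, or 0.01 without HFD replicate 1, but a mean just below 0). The riser was Cyba, a subunit of the phagocyte oxidase, at 0.97 ± 0.16, a call lost without RD replicate 1 or 2 (adjusted p up to 0.060), while 2 members rose without HFD replicate 2. The falls numbered 0 without each single RD array and 1 without HFD replicate 1 or 2.

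Drug metabolism and stress genes rose in smaller numbers. Of 23 CAR and PXR responsive genes 4 rose and 1 fell (8 and 2 adjusted over the list alone), among them Gadd45b, Cyp2c55 and the carboxylesterase Ces2a (0.95 ± 0.09). The fall was that of Nr1i3 (-0.30 ± 0.06), which encodes the receptor CAR and is named after its values were seen; it did not pass when any 1 array was left out. Camera called the list higher (adjusted p = 0.0084; adjusted p = 0.320 with an estimated correlation), a call lost without HFD replicate 3 (adjusted p = 0.051). In the unfolded protein and integrated stress response list 3 of 24 rose (5 adjusted over the list alone), including Atf3 (1.17 ± 0.10) and the asparagine synthetase Asns (1.39 ± 0.21), and camera called it higher (adjusted p = 7.2e-04; adjusted p = 0.378 with an estimated correlation). Of 12 cytosolic heat shock genes 4 rose (6 adjusted over the list alone), led by Hspb1 (1.07 ± 0.16), and the count was 1 without RD replicate 1 or 2 or HFD replicate 1 or 2 and 2 without RD replicate 3. Among 16 immediate early genes 3 rose (6 adjusted over the list alone), including Klf6 (0.95 ± 0.08) and Jun (0.81 ± 0.12). Camera called the heat shock list (adjusted p = 0.0022; adjusted p = 0.301 with an estimated correlation) and the immediate early list (adjusted p = 4.3e-04; adjusted p = 0.115 with an estimated correlation) higher. Among the brighter genes camera lost its calls of the immediate early list (adjusted p = 0.081) and the CAR and PXR list (adjusted p = 0.069).

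**Figure D3:**
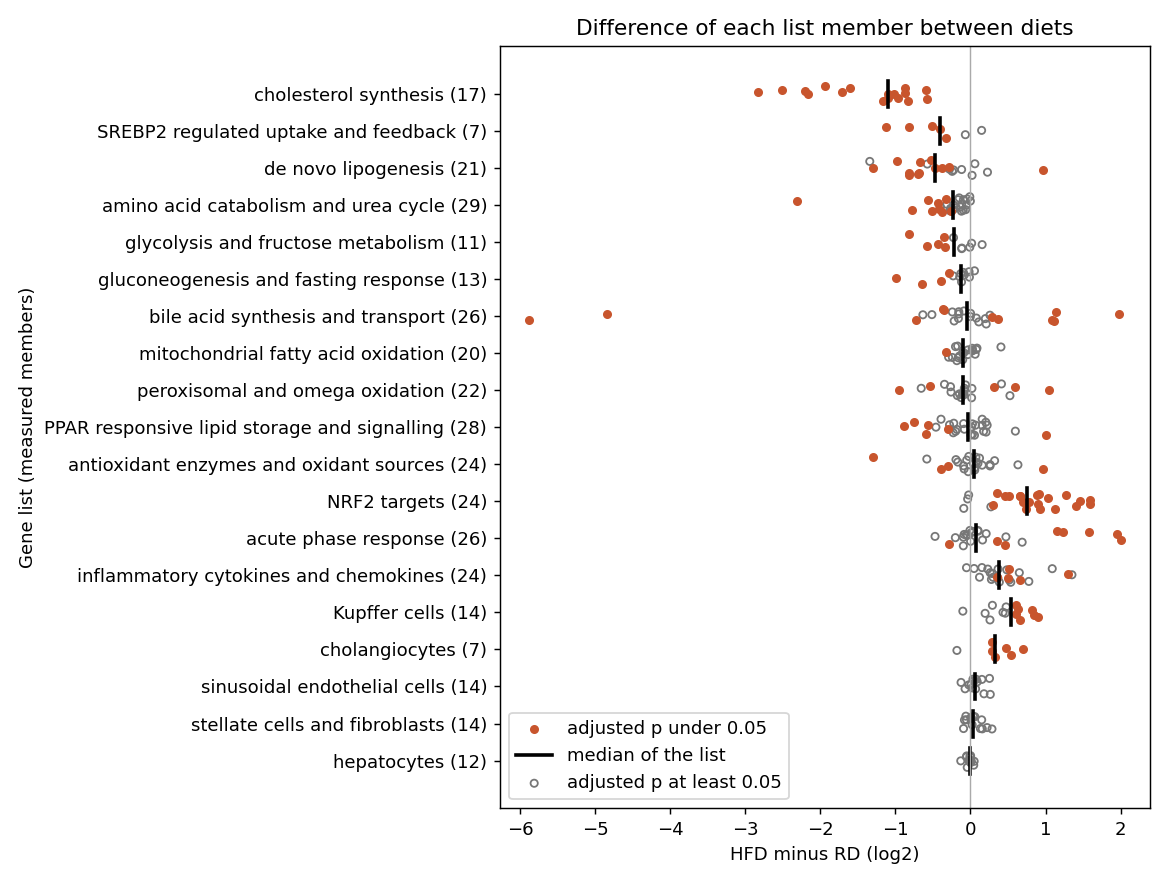
Log2 difference between HFD and RD for each measured member of 19 gene lists; filled points passed an adjusted p of 0.05, open points did not, and black bars are list medians. All 17 cholesterol synthesis genes lie below 0, and 20 of 24 NRF2 targets lie above 0 as filled points.

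Some inflammatory genes and macrophage markers rose in HFD. In the acute phase list 7 of 26 rose and 1 fell (7 and 2 adjusted over the list alone), with the lipopolysaccharide binding protein Lbp at 0.47 ± 0.07 beside the 3 serum amyloid genes. Without RD replicate 1 the count of risers was 4. The fall was that of Serpina3n (-0.29 ± 0.07), named after its values were seen, and was lost whichever array was left out (adjusted p up to 0.133), while another member fell without RD replicate 2. Of 24 inflammatory cytokines and chemokines 5 rose (14 adjusted over the list alone), 23 had a positive difference, and the median was 0.38. Il1a rose by 0.51 ± 0.09, a call lost without RD replicate 1 or 2 (adjusted p up to 0.071). The cytokine count was 1, 0 and 1 without RD replicate 1, 2 or 3 and 3 without HFD replicate 2. Camera called the acute phase list (adjusted p = 0.0071; adjusted p = 0.480 with an estimated correlation) and the cytokine list (adjusted p = 2.2e-09; adjusted p = 0.251 with an estimated correlation) higher. The acute phase median was only 0.07, with 17 positive and 9 negative differences. Its camera call was lost among the brighter genes (adjusted p = 0.129). Of 14 markers of Kupffer cells, the resident liver macrophages, 7 rose (12 adjusted over the list alone), with a median of 0.54, Cd5l at 0.85 ± 0.12 and the iron exporter Slc40a1 at 0.61 ± 0.07. Their count was 2, 2 and 3 without RD replicate 1, 2 or 3 and 3 without HFD replicate 3. Among 12 markers of monocytes and neutrophils 2 rose, also 2 adjusted over the list alone, including Cd14 (0.52 ± 0.07), and 1 rose without each single RD array. Both marker lists were called higher by camera (adjusted p = 9.1e-09 and adjusted p = 0.0012; adjusted p = 0.251 with an estimated correlation for each). Of the 12 monocyte and neutrophil markers only 1 had an RD level above the median of all genes. Their camera call was lost among the brighter genes (adjusted p = 0.138).

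Antigen presentation and interferon stimulated genes gave fewer calls. None of 15 antigen presentation genes passed in limma (0 adjusted over the list alone, 2 at an unadjusted p under 0.05), although 15 had a positive difference and the median was 0.35. Camera called that list higher (adjusted p = 0.0021; adjusted p = 0.572 with an estimated correlation), and without HFD replicate 1 the call was lost (adjusted p = 0.091) and the median was 0.10. Of 26 interferon stimulated genes 2 rose, Bst2 (0.38 ± 0.08) and Ddx58 (0.45 ± 0.09), and camera made no call (adjusted p = 0.130). Adjusted over that list alone 2 rose and 1 fell. Both calls were lost without RD replicate 1 or 2 or HFD replicate 1 or 3 (adjusted p up to 0.094), 1 was left without RD replicate 3 or HFD replicate 2, and without HFD replicate 1 there were 2 falls. Camera called the interferon list higher without RD replicate 3 (adjusted p = 0.044), HFD replicate 2 (adjusted p = 0.0050) or HFD replicate 3 (adjusted p = 0.036). Complement and coagulation genes leaned the other way, with 2 of 25 lower, also 2 adjusted over the list alone, and a median of -0.09, or -0.06 without HFD replicate 3. Camera called them lower (adjusted p = 0.0064; adjusted p = 0.480 with an estimated correlation), except without HFD replicate 3 (adjusted p = 0.133). When 1 array was left out, 1 member passed without HFD replicate 2 and 0 without each other array.

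The genes of amino acid and carbohydrate metabolism that passed were lower in HFD. All 29 genes of amino acid catabolism and the urea cycle had a negative difference, and 9 fell (17 adjusted over the list alone), including Bhmt, the glycine methyltransferase Gnmt (-0.57 ± 0.07) and the transaminase Agxt (-0.78 ± 0.11). The count was 4 without each single RD array or HFD replicate 2 and 5 without HFD replicate 1. Of 13 genes of gluconeogenesis and the fasting response 4 fell, also 4 adjusted over the list alone, with the aspartate transaminase Got1 lower by 1.99-fold and the glucose phosphatase G6pc at -0.65 ± 0.09. Of 11 genes of glycolysis and fructose metabolism 5 fell (6 adjusted over the list alone), including the fructokinase Khk (-0.44 ± 0.07). The gluconeogenesis count was 2 without each single array but HFD replicate 3, and the glycolysis count was 2, 1 and 3 without RD replicate 1, 2 or 3 and 3 without each single HFD array. In the oxidative phosphorylation list 2 of 34 genes fell (4 adjusted over the list alone), 30 had a negative difference and the median was -0.13; no member passed when any 1 array was left out. Camera called these 4 lists lower, with adjusted p = 2.5e-12 for amino acids, 9.2e-05 for gluconeogenesis, 1.7e-04 for glycolysis and 1.4e-06 for oxidative phosphorylation. With an estimated correlation the adjusted p was 0.166, 0.161, 0.116 and 0.251 in the same order.

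Clock, cell cycle, iron and sex-biased genes were also tested. Of 19 circadian genes 3 fell (5 adjusted over the list alone), led by Hlf (-0.58 ± 0.07), which alone passed without 1 array, and camera called the list lower (adjusted p = 0.0061; adjusted p = 0.251 with an estimated correlation). Of 28 cell cycle genes 1 rose, Ccnd1 (0.57 ± 0.13; 4 adjusted over the list alone), a call lost without RD replicate 2 or 3 or HFD replicate 1 or 3. In this list 3 members rose without RD replicate 3 and 2 without HFD replicate 2. Camera's call of that list as higher (adjusted p = 0.049; adjusted p = 0.717 with an estimated correlation) was lost without RD replicate 1 or 2 or HFD replicate 3 (adjusted p up to 0.672), and the median of 0.10 became -0.07 without RD replicate 2 and -0.04 without HFD replicate 3. Among 14 iron handling genes 2 rose and 1 fell (4 and 2 adjusted over the list alone), including Slc40a1 and the transferrin receptor Tfrc (0.94 ± 0.14), with no call by camera (adjusted p = 0.141); the fall, of Hamp2 (-0.87 ± 0.14), a paralog of the hepcidin gene Hamp, was lost without RD replicate 1. Of 18 male biased liver genes 1 rose and 3 fell (2 and 5 adjusted over the list alone), with Selenbp2 at -1.51 ± 0.15 and Susd4 at -1.24 ± 0.11, and camera called the list lower (adjusted p = 0.0012; adjusted p = 0.460 with an estimated correlation). Without HFD replicate 2 there were 5 falls, and 1 member rose without RD replicate 1 but 0 without each other array. Of 17 female biased genes 1 rose and 2 fell, Cyp17a1 and Atp6v0d2 (-1.56 ± 0.23), with 2 and 2 adjusted over the list alone and no call by camera (adjusted p = 0.750); 3 rose without HFD replicate 2. None of 4 sex chromosome genes passed in limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05; camera adjusted p = 0.379).

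Markers of the other cell types of the liver moved unequally. None of 12 hepatocyte markers passed in limma (0 adjusted over the list alone, 0 at an unadjusted p under 0.05; median -0.00), and camera made no call (adjusted p = 0.655). Of 13 pericentral hepatocyte markers 1 rose and 5 fell (2 and 8 adjusted over the list alone), including the ammonium transporter Rhbg (-0.95 ± 0.15) and Gulo (-0.45 ± 0.07). Camera called this list lower (adjusted p = 5.1e-04; adjusted p = 0.115 with an estimated correlation), and 2 members fell without RD replicate 2 or HFD replicate 1 and 3 without RD replicate 1 or HFD replicate 2. The rise was lost without RD replicate 2. Among 9 periportal markers 1 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.750; median -0.02, from -0.04 to -0.01 without 1 array, but mean 0.01). When 1 array was left out, 1 fell without HFD replicate 3 and none passed otherwise. Cholangiocyte markers, of the bile duct lining, rose in 6 of 7 cases, also 6 adjusted over the list alone, with a median of 0.33 and Krt19 at 0.70 ± 0.14. Camera called them higher (adjusted p = 1.7e-04; adjusted p = 0.115 with an estimated correlation), yet 0 passed without RD replicate 1 and 1 without each other array. None of 14 sinusoidal endothelial markers (median 0.06; camera adjusted p = 0.160) and none of 14 stellate cell and fibroblast markers (median 0.03; camera adjusted p = 0.401) passed, with 0 adjusted over either list alone and 2 of each at an unadjusted p under 0.05. No call was made in limma either for 13 T and NK cell markers (median 0.23; camera adjusted p = 0.054; 1 at an unadjusted p under 0.05), 9 B and plasma cell markers (median -0.05; camera adjusted p = 0.280; 1 likewise) and 3 erythroid markers (median -0.18; camera adjusted p = 0.178; 0 likewise), with 0 adjusted over each list alone. The T and NK cell list had a median of 0.08 without HFD replicate 1 (camera adjusted p = 0.677) and of 0.36 without HFD replicate 2, where camera called it higher (adjusted p = 3.0e-04). Other medians of lists that camera did not call turned sign when 1 array was left out. The endothelial median was -0.01 without HFD replicate 1, the stellate median -0.02 without RD replicate 1 or HFD replicate 1, the B cell median 0.02 without HFD replicate 2 and the hepatocyte median 0.01 without HFD replicate 3. The erythroid median was -0.09 without RD replicate 3 and -0.10 without HFD replicate 1. Of 9 adipocyte markers 2 fell, also 2 adjusted over the list alone, including Car3 (-0.41 ± 0.07), which hepatocytes express too. That call was lost without RD replicate 1 (adjusted p = 0.058), and 1 adipocyte marker fell without each single array but HFD replicate 1. Camera called the adipocyte list lower (adjusted p = 0.0085; adjusted p = 0.251 with an estimated correlation). Of 11 pancreatic acinar markers 1 rose, Reg1 (0.82 ± 0.16; 1 adjusted over the list alone), a call lost without RD replicate 1 or each single HFD array. Camera gave that list no call and the direction lower (adjusted p = 0.987), while its median of 0.02 and mean of 0.03 were positive; the median was -0.01 without RD replicate 2 and -0.02 without HFD replicate 3.

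Over the 43 lists camera called 12 higher and 15 lower with its preset correlation of 0.01, and none with an estimated correlation, where 10 lists had an unadjusted p under 0.05. Fry, which tests whether a list's genes move one way on balance, called 9 higher and 13 lower, and 20 of these were camera calls of the same direction. Fry but not camera called bile acid synthesis and transport lower (adjusted p = 0.014) and iron handling higher (adjusted p = 0.023). It did not make 7 of the camera calls. These were PPAR responsive lipid storage, unfolded protein and integrated stress response, acute phase, antigen presentation, complement and coagulation, cell cycle and male biased genes.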

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

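The tests of explanations in this part were chosen after the results were seen, except the test of unequal marker changes.

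Some rows outside the gene comparison passed the threshold. Of the 12102 rows not listed with a gene, 39 passed an adjusted p of 0.05 when every row of the table was tested, 12 higher and 27 lower in HFD, but 4 passed when these rows were tested on their own. Of the 1621 rows listed with several genes 14 passed, 9 higher and 5 lower.

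The fall of the cholesterol synthesis genes was set against 3 technical explanations. If the normalization by the authors were the whole source, fewer than 12 of the 17 members would stay lower after other scalings. All 17 stayed lower under both quantile normalization and median centring. However, array medians already lay between 7.06 and 7.11, while the smallest fall in the list was 0.59. These rescalings could hardly lose a member and cannot undo the authors' unstated steps, so normalization is not excluded. A trend of the difference with signal level would also move other genes of like signal, yet 0% of 10000 random lists matched on mean signal had a median as low as -1.10, and the lowest was -0.23. A single array does not carry it, since 16 or more members stayed lower without each array in turn. A biological fall remains a hypothesis, found and tested on the same data, and batch effects were not tested.

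The rise of Kupffer cell markers, whose list call was lost with an estimated correlation (adjusted p = 0.251), was weighed against a lower share of hepatocyte RNA, a single array and a larger share of unchanged macrophages. A lower hepatocyte share would raise endothelial and stellate markers as much, but the mean of the 14 Kupffer cell markers minus that of 28 endothelial and stellate markers was 0.38 ± 0.18 log2 in HFD and -0.06 ± 0.03 in RD (SD, n = 3 each; two-sided exact permutation test over arrays, p = 0.1, the smallest that 6 arrays allow), with no overlap between diets; permuting markers gave 1e-05, the smallest that 100000 resamples can give, but treats markers as independent, which overstates the support. The endothelial and stellate lists were chosen after their medians of 0.06 and 0.03 were seen, so the contrast was already in view. Other non-hepatocyte lists were left out, with medians of 0.33 for cholangiocytes, 0.22 for monocytes and neutrophils and 0.23 for T and NK cells. The median was -0.05 for B and plasma cells, -0.18 for erythroid cells, -0.17 for adipocytes and 0.02 for acinar cells. A lower hepatocyte share is therefore not excluded. Without each array in turn the median of the Kupffer cell markers stayed at 0.396 or more. The highest camera adjusted p with the preset correlation was then 5.3e-07. However, the 7 Kupffer cell markers that passed became 2, 2 and 3 without RD replicate 1, 2 or 3 and 3 without HFD replicate 3. A larger share alone would raise all markers by 1 factor, whereas their differences ran from -0.10 to 0.89 (Cochran's Q test over n = 14 markers, p = 8.3e-08). That test takes the SEs as known and the markers as independent, although all come from the same 6 arrays. Its p is therefore uncertain. Probe sets can also compress changes unequally, so a larger share remains open as part of the rise. A change of expression within macrophages may contribute and was not tested separately, and 13 of the 14 markers lie above the median of all genes in RD liver, 1 being in another list.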

How the results depend on the processing

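No alternative was added after the data were seen. The 1067 called genes kept their direction in each alternative that was compared gene by gene, which leaves out every row and the fold thresholds, and 918 of them were among the brighter genes. Most of these alternatives could not turn a sign. No call overlapped between diets, so leaving out or weighting arrays keeps the direction. The brighter genes, trend, block and unmoderated settings keep the same difference. Only quantile normalization, median centring and mean probe sets could have turned it. The numbers of genes higher in HFD and genes lower in HFD stayed within 1.5 times 621 and 446 under quantile normalization, median centring, the brighter genes, mean probe sets, trend with robust prior and array weights (619 to 862 higher, 384 to 619 lower). Testing every row gave 168 and 173; those rows include 12102 without a gene, whose median residual SD was 0.172 against 0.101 for the genes tested, and the prior degrees of freedom went from 4.37 to 2.60. The unmoderated model gave 41 and 58, having no shared variance estimate. Requiring 1.5-fold with an adjusted p under 0.05 gave 208 and 151 by construction, and 1.5-fold with an unadjusted p under 0.05 gave 264 and 173. Without 1 array, with fewer samples, higher genes numbered 197 to 371 and lower genes 178 to 273, and 389 to 551 of the 1067 calls were kept. With the replicate number as a replicate block the counts were 318 and 245, with 521 of the 1067 calls kept; the block spends degrees of freedom. Nothing in the labels says that the numbers pair mice: deviations of same-numbered arrays correlated at -0.11, 7.2e-05 and 0.12, and 1 of 3 numbers had arrays that correlated best with each other. Lists called higher numbered 6 among the brighter genes, where fewer genes were tested, against 12, and lists called lower 13 against 15. With an estimated correlation 0 lists were called in either direction, against 12 and 15, and the cause was not tested. Without 1 array 11 to 14 lists were higher and 13 or 14 lower. The adjusted p with an estimated correlation was the highest over all alternatives for 25 of the 27 called lists, the others being cholangiocytes and adipocytes, where the brighter genes gave 0.121 and 0.253, and 13 of the 27 passed in every other alternative. Over 101 named genes, 1240 values kept their direction and side of the threshold and 166, from 81 genes, no longer passed, and no named gene turned sign. For called genes the sign was fixed beforehand in most of these settings, as said above. For lists 548 kept both, 61 from 27 lists no longer passed, 8 from 4 lists newly passed, and 28 from 10 lists turned the sign of the median or the direction of the test; the cause was not tested. Of these 10 lists camera had called only cell cycle, whose median of 0.10 ran from -0.071 to 0.36 without 1 array. The others had medians, without 1 array, of 0.014 to 0.050 for antioxidants, 0.0061 to 0.16 for interferon, -0.062 to 0.12 for female biased genes, -0.019 to 0.0068 for hepatocytes, -0.0065 to 0.10 for endothelium, -0.021 to 0.075 for stellate cells, -0.081 to 0.015 for B cells and -0.024 to 0.039 for acinar cells. With median centring the median was 0.019 for female biased genes, 0.017 for hepatocytes and 0.0020 for periportal cells; with quantile normalization it was 0.023 for female biased genes and 0.037 for acinar cells. Among the brighter genes it was 0.041 for B cells, -0.32 for acinar cells and 0.046 for antioxidants, where camera turned to lower. For acinar cells it was -0.0052 with array weights and 0.020 with fry, which gave the direction higher. The signal over background that would limit dim genes was not measured here.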

Other observations

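The gene lists in this part were chosen after the data had been seen, and so were the tests made on the lists of LXR targets.

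The keratins Krt8 and Krt18, the tubulin Tubb2a, the annexin Anxa2 and S100a6 were higher in HFD. Of 13 keratins, tubulins, annexins and related genes 5 rose (11 adjusted over the list alone), 13 had a positive difference, and the median was 0.68. Tubb2a rose by 1.35 ± 0.14 (log2, SE), Anxa2 by 1.28 ± 0.10, Krt8 by 0.74 ± 0.07 and Krt18 by 0.68 ± 0.08. Lipid-associated macrophage genes leaned the same way, with 6 of 15 higher (8 adjusted over the list alone) and a median of 0.56. Mmp12 rose by 1.17 ± 0.17, Lgals3 by 0.95 ± 0.15 (a call lost without RD replicate 2) and Cd9 by 0.93 ± 0.12, while Trem2 stood at -0.08 ± 0.07. In the same arrays Kupffer cell markers had a median of 0.54, and cholangiocyte markers, 6 of 7 of which rose, had a median of 0.33, with Krt19 at 0.70 ± 0.14. Bile duct and other non-parenchymal cells express several of these keratins and annexins too, so the cell type behind the rise is open.

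One-carbon and methyl metabolism shifted in both directions. Of 16 genes 7 fell and 2 rose (8 and 3 adjusted over the list alone), with Gamt at -0.84 ± 0.06, Sardh at -0.57 ± 0.07 and the choline kinase Chka at 0.99 ± 0.12, beside Bhmt. Among 15 retinol dehydrogenases and related enzymes 4 fell and 1 rose (5 and 2 adjusted over the list alone), with Rdh16 at -1.05 ± 0.09, Rdh16f2 at -0.94 ± 0.11 and Rdh9 at 0.52 ± 0.10, a call lost without RD replicate 1 or HFD replicate 1 or 3. The cytoskeletal, macrophage, one-carbon and retinol lists hold genes already seen to change, so no result of camera or fry is given for them. Their counts adjusted over the list alone are raised by that choice. These counts describe the lists and are no support for a change of the list.

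Since Cyp26a1 and Dhrs9 rose, higher retinoic acid signalling was tested as a hypothesis on 12 other genes that retinoic acid induces. Camera gave an unadjusted p of 0.729 with a median of -0.07 and a 95% bootstrap interval of -0.14 to 0.13, which leaves the hypothesis undecided. Of these genes 1 rose (2 adjusted over the list alone), Tgm2 (0.49 ± 0.10), a call that held only without HFD replicate 3 when 1 array was left out. The bootstrap interval above and the intervals below resample the genes of a list and not the arrays. They treat genes as independent and do not give the uncertainty of the diet effect. An amino acid response through ATF4 was tested on 23 other targets after Asns, Psat1, Mthfd2 and Aldh18a1 had been seen to rise. Its targets may have risen together: camera gave an unadjusted p of 1.6e-05 and, over the 7 added lists, an adjusted p = 3.8e-05, the median was 0.21 with an interval of 0.12 to 0.27, 20 of 23 differences were positive and 3 passed over all genes (11 higher and 1 lower adjusted over the list alone), though with an estimated correlation the unadjusted p was 0.030 and the adjusted p = 0.064. Chac1, Ddit3, Sesn2 and Trib3 of these 23 targets also belong to the stress response list that camera had already called higher. Cth belongs to the amino acid list. The test thus reuses genes already examined and gives no independent support. Both adjusted p-values were taken over 7 lists, some of which hold genes already seen to change. The small p-values of such lists lower both adjusted values, so neither adds support. The call of Mthfd2 was lost without RD replicate 1 or 2 or HFD replicate 3. LXR activation, raised by Abcg5, Abcg8 and Abcg1, was tested on 14 other targets and stays undecided, with an unadjusted p of 0.129 and a median of 0.07 (interval -0.05 to 0.35). Of these targets 3 rose, Srebf1 (0.97 ± 0.22), Scd2 (0.93 ± 0.12) and Abca1 (0.58 ± 0.10), and Pltp fell by 1.08 ± 0.11 on the log2 scale (3 higher and 2 lower adjusted over the list alone). The call of Abca1 was lost without RD replicate 2 or 3, and that of Srebf1 held only without RD replicate 3.

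The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The diets gave 621 higher and 446 lower genes, and the highest of the other splits gave 0 and 0, with at most 1270 genes at an unadjusted p under 0.05 against 3926; 1 of 10 splits, the real one, reached each count. For lists the diets gave 12 higher and 15 lower, and the highest other splits gave 11 and 9, so camera with its preset correlation called many lists for groupings other than diet. Each of those groupings mixes the diets and keeps part of the diet difference. Mixing also puts diet differences within groups, which widens the residual and lowers the gene counts. The 0 gene calls therefore do not show what groups without a diet difference would give. The source of the list calls was not tested.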
